A study of Mus musculus with 6 samples.

How the data were processed

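Messenger RNA libraries (TruSeq RNA v2, total RNA) were made from 6 samples of mouse epidermal keratinocytes, 3 labelled WT and 3 labelled iKO, per the labels' protocols. The submitters' processing notes name TopHat2, HTSeq, DESeq2 and DESeq without versions, and the build mm10. Annotation, strand setting and read length are not given in the sources used here. The deposited table holds whole-number counts of reads per gene symbol, not normalised, for 23420 genes. It also holds the 5 HTSeq summary rows, which made up 27.4% to 35.5% of all counts per library and were left out of library sizes and tests. A second deposited table has the columns of a DESeq2 result per the file headers: a mean normalised signal, a log2 fold change with its SE, a Wald score, and unadjusted and adjusted p-values. The authors' settings for it are not given in the sources used here. In that table the summary rows were left in and 27 gene names had been turned into dates; those names were not matched. Its fold changes are positive where counts were higher in the libraries labelled iKO.

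Columns were assigned to libraries by the number in their names. The column named with 33 matches no iKO title, so it was used as a replicate of the iKO group without a number of its own. No pair of libraries within a group agreed within sampling noise: the smallest chi-square per degree of freedom over genes was 51.7.

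Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its minimum count of 10, which left 12672, libraries were scaled by TMM factors, and groups were compared by glmQLFit and glmQLFTest with robust estimation, two-sided, with Benjamini-Hochberg adjustment at 0.05. The model held the group as its only term. Fold changes are given as libraries labelled iKO minus libraries labelled WT, and their SE is approximate, the absolute log2 fold change divided by the square root of the F statistic. Normalised CPM values use the TMM-scaled library sizes, and log2 CPM values a prior count of 2. A gene with no count in a group was set against a floor of 3 counts over all libraries of that group together, which covers counting error only. Libraries of 21943467 to 83337263 gene counts differ in what 3 counts in a single library amount to, between 0.0353 and 0.138 CPM.

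Before the data were examined, 29 gene lists were fixed: 26 on pathways, keratinocyte states and other cell types, and 3 checks on sex-linked, mitochondrial and ribosomal protein genes. Lists with at least 5 tested genes were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. Gata6 was left out of all lists. This left 22 lists, adjusted together, with the checks adjusted apart. Single genes were also adjusted within their list alone, with no correction across lists. A pass of that kind is weaker than a pass over all genes. The genes to name were also fixed by rule: Gata6, Edaradd, Edar and Eda; the 10 genes raised and 10 lowered with the largest change among those past the threshold with mean log2 CPM of at least 1 and no overlap between groups; up to 4 members of each list with the smallest p; and the 5 raised and 5 lowered genes with the smallest p. Predicted gene models were left out, and 1 of the 23 called genes that the rule takes is not reported here. Mcm7, Pcna, Col1a1, Dcn, Lum, the neighbours of Edaradd and the genes that open the other observations were chosen after their values were seen.

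Gene positions come from the GENCODE mouse annotation on mm10, in which 23303 symbols (99.5%) were found. The test was checked on simulated data, negative binomial counts drawn from each gene's mean over the 6 libraries, its dispersion and the library sizes, with changes put into genes with a mean above 5 CPM. There edgeR recovered 61 of 100 genes changed by a factor of 2 and 97 of 100 changed by a factor of 4, with 15 false calls among 12525 tested genes. DESeq2 1.42.0 recovered 78 and 98, with 58 false calls among 12672. With no change simulated, edgeR called 0 of 12535 genes and camera 0 of 22 lists; those counts were drawn without correlation between genes.

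Alternatives fixed before the data were examined were other scaling factors, other count filters, DESeq2, limma-voom, no robust estimation, a block on replicate number, other thresholds, a fold minimum, an estimated correlation for lists, and leaving out each library. Leaving out genes of the X and Y chromosomes, leaving out genes of chromosome 1, a block of the 2 deepest libraries, the 4 libraries numbered 3 and 4 without a block, and DESeq2 with a prior on fold changes were added after seeing the data.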

Results

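Gene expression was measured by mRNA sequencing in cultured mouse epidermal keratinocytes, the cells that form the outer layer of the skin. All 6 samples carried loxP-flanked alleles of Gata6, a zinc finger transcription factor of the GATA family. The 3 libraries labelled iKO (induced knockout) also carried K14-CreERT2, a tamoxifen-activated Cre recombinase driven by the keratin 14 promoter, and the 3 libraries labelled WT did not. Cells of both groups were kept in low-calcium medium to passage 8 to 10 and received 1 µM 4-hydroxytamoxifen for 6 hours. Reads assigned to genes numbered 21943467 in WT 2, 79055307 in WT 3, 34047196 in WT 4, 32751896 in iKO 3, 44784847 in iKO 4 and 83337263 in iKO 33, the iKO library whose column bears the number 33. The labels do not say whether libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Pearson correlations of log2 CPM (gene counts scaled to the size of the library) across genes were 0.966 to 0.982 within groups and 0.946 to 0.977 between groups, and genes are not independent replicates.

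The comparison asks which transcripts differ between keratinocytes with and without induced deletion of Gata6. The targeted gene went against the labels: Gata6 (chromosome 18, 11052064 to 11085635, plus strand, mm10) was higher in the libraries labelled iKO. Its normalised CPM was 2.86 in WT 2, 0.519 in WT 3 and 5.37 in WT 4, against 14.2 in iKO 3, 21.02 in iKO 4 and 17.0 in iKO 33. The group values were 2.92 ± 2.43 and 17.4 ± 3.44 (SD, n = 3), a log2 fold change of 2.60 (SE 0.72) that was 2.07 without WT 3 and 3.47 without WT 4. The difference did not pass edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (adjusted p = 0.180), and it passed in DESeq2 (adjusted p = 0.00134; up to 0.644 over the other alternatives). The counts are per gene and can include reads from exons outside the deleted part, so they do not check whether the floxed exons were lost. Groups are therefore named by their labels throughout, and every direction below is that of the libraries labelled iKO relative to those labelled WT.

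**Figure D1:**
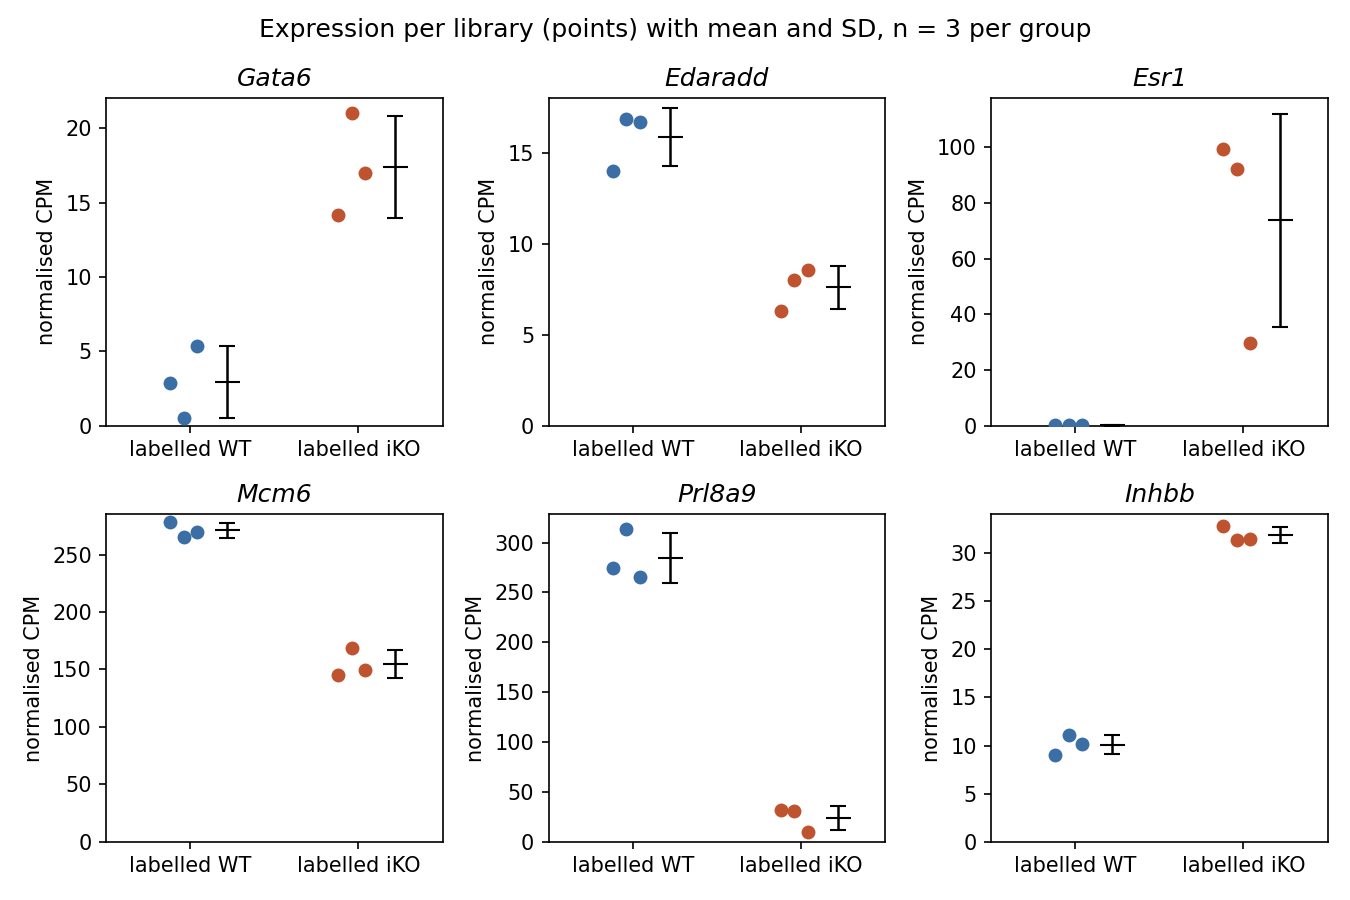
Normalised CPM (y axes, linear, from 0) of 6 genes in each library (points), with the group mean and SD (black, n = 3). Gata6 lay between 14.2 and 21.02 in the libraries labelled iKO, all above those labelled WT, and Edaradd lay lower in the libraries labelled iKO.

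Edaradd, the adaptor that links the ectodysplasin receptor Edar to NF-κB signalling and is named in the title of the study, was at a lower level in the libraries labelled iKO. Edaradd (chromosome 13, 12472632 to 12520438, minus strand, mm10) measured 15.9 ± 1.60 CPM in the libraries labelled WT and 7.62 ± 1.17 CPM in those labelled iKO (SD, n = 3), with no overlap. The log2 fold change was -1.06 (SE 0.18). It missed the threshold over all genes in edgeR (adjusted p = 0.0727) and passed in DESeq2 (adjusted p = 2.43e-05, and up to 0.557 over the other alternatives). In edgeR it passed when adjusted over its pathway list alone (adjusted p = 0.00871). Edaradd was already named in the title and called in the authors' deposited table of the same libraries, so that pass is no independent support. The receptor Edar (0.56, SE 0.42) and its ligand Eda (0.17, SE 0.26) did not pass in edgeR (adjusted p = 0.586 and 0.808). Of the 16 genes of the EDA and NF-κB pathway list, 8 were higher and 8 lower, and Edaradd was the 1 member that passed when adjusted over the list alone. Of 22 tested NF-κB target genes, 10 were higher and 12 lower, and none passed in edgeR, over all genes or adjusted over the list alone; 3 had an unadjusted p under 0.05 and DESeq2 called 3. Among them Birc3, an inhibitor of apoptosis, had a log2 fold change of -2.43 (SE 0.62), the cytokine gene Tnf of -3.42 (SE 1.11) with overlapping groups, and Bcl3, an NF-κB cofactor, of 1.44 (SE 0.48). Single libraries moved these values: Birc3 stood at -3.54 without iKO 33, Tnf at -1.95 without WT 4 and -4.15 without iKO 33, and Bcl3 ranged from 1.05 without WT 3 to 1.96 without WT 4.

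The tested neighbours of Edaradd also had lower values in the libraries labelled iKO. All 9 other tested genes within 1 Mb had negative log2 fold changes, among them Heatr1 at -0.43 (SE 0.15), Lgals8 at -0.30 (SE 0.12) and Ero1lb at -0.95 (SE 0.23). Gpr137b-ps stood at -1.35 (SE 0.28), Prl2c2 at -1.07 (SE 0.56), Prl2c5 at -4.24 (SE 0.51) and Gpr137b at -0.90 (SE 0.30). These 4 genes have near-identical copies in the same window, so their counts are uncertain, and of the 9 neighbours only Prl2c5 passed in edgeR (adjusted p = 0.0324). The median of the 9 was -0.90, and it was -0.40 over the 5 genes without such copies. Tested genes of chromosome 13 outside the window had a median of -0.18. Farther along the chromosome, past Lyst (-0.29, SE 0.28), the values of B3galnt2 (0.02, SE 0.13), Tbce (0.03, SE 0.16) and Ggps1 (0.14, SE 0.17) were closer to 0, and Arid4b stood at 0.68 (SE 0.27).

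**Figure D2:**
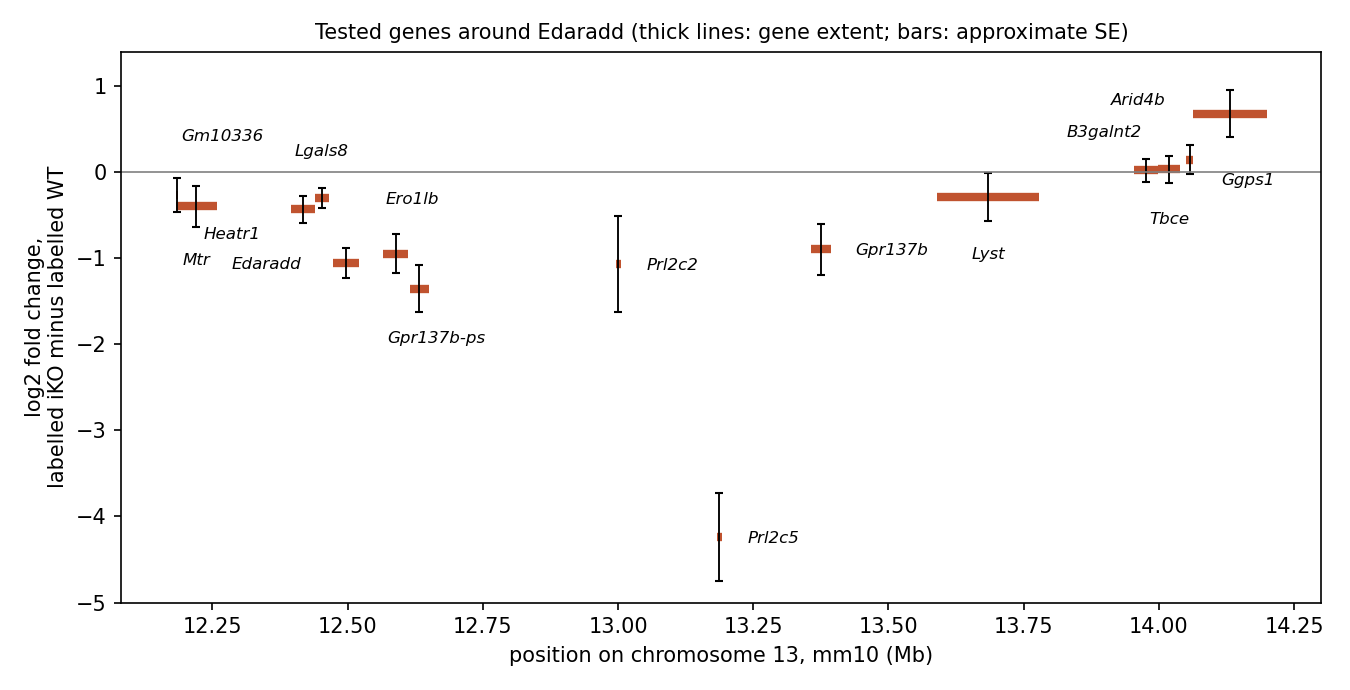
Log2 fold change (y axis, libraries labelled iKO minus labelled WT) of tested genes against their position on chromosome 13 in Mb (x axis, mm10); thick lines span the gene and bars give the approximate SE. Values from Edaradd to Gpr137b ranged from -4.24 (Prl2c5) to -0.90 (Gpr137b), and the genes beyond Lyst lay at 0.02 or above.

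Across the transcriptome, 43 of 12672 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 29 of them higher and 14 lower in the libraries labelled iKO. Among autosomal genes that rose, Efemp2, an extracellular matrix fibulin gene, rose by 3.52 on the log2 scale (SE 0.42), the oxidoreductase gene Htatip2 by 3.24 (SE 0.41) and the galactosyltransferase gene B4galt4 by 2.80 (SE 0.25). Exo5, a single-stranded DNA exonuclease, rose from 2.05 ± 0.401 to 9.92 ± 0.566 CPM (SD, n = 3). Inhbb, which encodes an activin and inhibin subunit (chromosome 1, 119415465 to 119422248), rose from 10.1 ± 1.02 to 31.8 ± 0.853 CPM. Among genes that fell, the glycosyltransferase genes Gyltl1b and B3gnt3 fell by 4.33 (SE 0.45) and 2.97 (SE 0.20) on the log2 scale. Tagap, a GTPase-activating protein gene, fell by 4.87 (SE 0.43) from a level of 1.38 ± 0.246 CPM. Prl8a9, a prolactin family gene, fell from 284 ± 25.4 to 24.3 ± 12.2 CPM, and it and Prl2c5 belong to a multigene family whose members can share reads. Ntm, a neuronal adhesion molecule gene, fell by 1.71 (SE 0.22), the transcription factor gene Sox21 by 1.60 (SE 0.22), the splicing factor gene Cwc22, whose copy number varies between mouse strains, by 1.38 (SE 0.12), and the cell division gene Cdca7 by 0.85 (SE 0.11). Mcm6, a subunit of the replicative helicase (chromosome 1, 128331590 to 128359664), fell from 271 ± 6.61 to 155 ± 12.4 CPM.

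**Figure D3:**
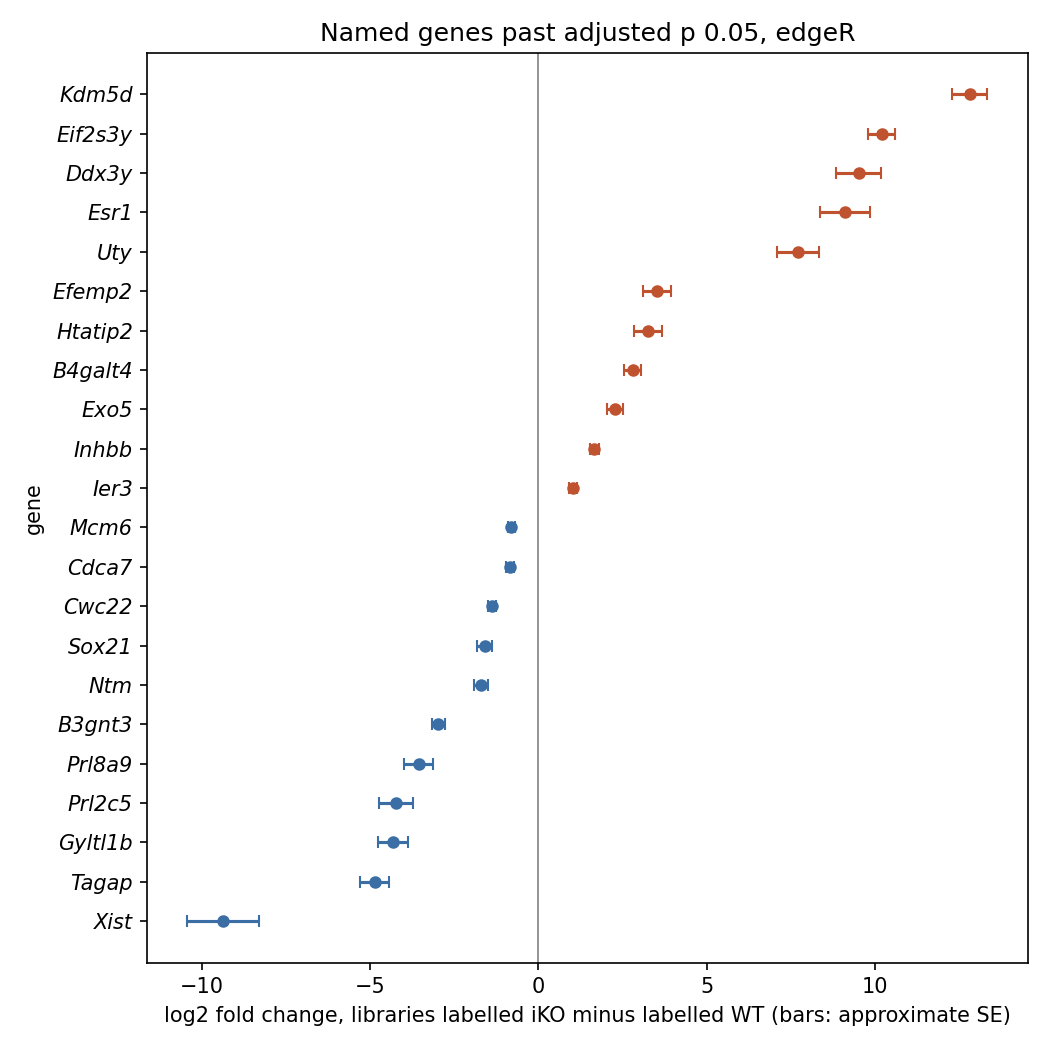
Log2 fold change (x axis, libraries labelled iKO minus labelled WT) of 22 named genes (y axis) past an adjusted p of 0.05 in edgeR, with points for the estimate and bars for the approximate SE. Eif2s3y lay at 10.19 and Xist at -9.37; the point for Kdm5d depends on the prior count, since it had no count in the libraries labelled WT.

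An unadjusted p under 0.05 was reached by 1904 genes in edgeR (928 higher, 976 lower). The groups did not overlap for 2769 genes, 21.9% of those tested. Chance gives 10% on average, but genes are not independent, so this share is no test. DESeq2 called 757 genes (399 higher, 358 lower), including all 43, though on simulated data it made more false calls than edgeR (58 against 15). In that single simulation, drawn with the dispersions of the edgeR fit, false calls exceeded a share of 0.05 of the calls in both tools. The edgeR count depended on single libraries: it was 7 without WT 2, 31 without WT 3, 21 without WT 4, 20 without iKO 3, 13 without iKO 4 and 17 without iKO 33. Of the 22 called genes named here, Kdm5d, Eif2s3y, Ddx3y, Uty and B3gnt3 passed in each of these 6 fits, and the other 17 lost the call in at least 1. Among these 17, Efemp2, Ntm, Sox21, Cdca7 and Mcm6 lost it whichever library was left out, and Prl2c5 and Prl8a9 passed in only 1 fit.

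Sex-linked transcripts separated the groups completely. Xist, the non-coding RNA expressed from the inactive X chromosome, stood at 736 ± 143 CPM in the libraries labelled WT and 1.17 ± 1.31 CPM in those labelled iKO (SD, n = 3). The Y-linked genes showed the opposite: Eif2s3y rose from 0.0264 ± 0.0254 to 45.1 ± 10.3 CPM, Ddx3y from 0.0745 ± 0.0698 to 36.7 ± 7.54 CPM and Uty from 0.0990 ± 0.114 to 15.8 ± 4.39 CPM. Kdm5d had no count in any library labelled WT and 18.1 ± 4.17 CPM in those labelled iKO, at least 818-fold higher when the WT group is set at a floor of 3 counts over its libraries. All 5 genes passed in edgeR (adjusted p between 0.000494 and 0.0267) and account for the 5 calls on the X and Y chromosomes. Sex of the cells therefore coincided with the genotype label in all 6 libraries, and the comparison cannot separate them. Esr1, which encodes oestrogen receptor alpha, rose from 0.147 ± 0.120 to 73.7 ± 38.3 CPM (log2 fold change 9.10, SE 0.75, edgeR adjusted p = 0.00678). CreERT2 contains a mutated ligand-binding domain of this receptor, and counts per gene do not show which part of the transcript the reads came from.

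Genes of DNA replication and repair were lower in the libraries labelled iKO. Of 40 DNA replication and S phase genes, 39 had a negative log2 fold change (median -0.39), 1 (Mcm6) passed over all genes in edgeR, and 14 passed when adjusted over the list alone. These included Mcm3 (-0.71, SE 0.13) and Mcm7 (-0.42, SE 0.10) of the replicative helicase, the S phase transcription factor gene E2f1 (-0.90, SE 0.14), Uhrf1 (-0.86, SE 0.19), which maintains DNA methylation at replication, and the sliding clamp gene Pcna (-0.52, SE 0.13). Of 59 DNA damage signalling and repair genes, 50 were lower (median -0.27), none passed over all genes, and 3 passed when adjusted over the list alone: the checkpoint kinase gene Chek1 (-0.77, SE 0.13), the exonuclease gene Exo1 (-0.86, SE 0.17) and Parp1 (-0.59, SE 0.12). An unadjusted p under 0.05 in edgeR was reached by 23 of the repair genes, and DESeq2 called 5. Of 36 G2/M and mitosis genes, 28 were lower (median -0.12), and none passed in edgeR in either adjustment; 7 had an unadjusted p under 0.05 and DESeq2 called 3. The library means of each list were 6.15 ± 0.11 against 5.75 ± 0.10 log2 CPM for replication, 5.11 ± 0.08 against 4.84 ± 0.14 for repair and 7.04 ± 0.01 against 6.90 ± 0.24 for mitosis (SD, n = 3). Exact two-sided permutation p-values were 0.1, 0.1 and 0.4, where 0.1 is the smallest that 3 against 3 libraries allow. Between the same groups, 35 of 38 ribosomal protein genes, taken here as a sign of RNA quality, were higher in the libraries labelled iKO. Library means of that list overlapped, with iKO 4 (9.50) below WT 3 (9.52 log2 CPM). Reads not uniquely aligned made up 24.2% of counts in the libraries labelled iKO against 30.0% in those labelled WT. Mcm6, Mcm3, Exo1 and Parp1 lie on chromosome 1, whose tested genes had a median of -0.25. Without the genes of chromosome 1 the replication median was -0.38 over 38 genes, 12 of them lower when adjusted over the list alone, and the repair median was -0.28 over 55 genes, 1 of them lower in that way.

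**Figure D4:**
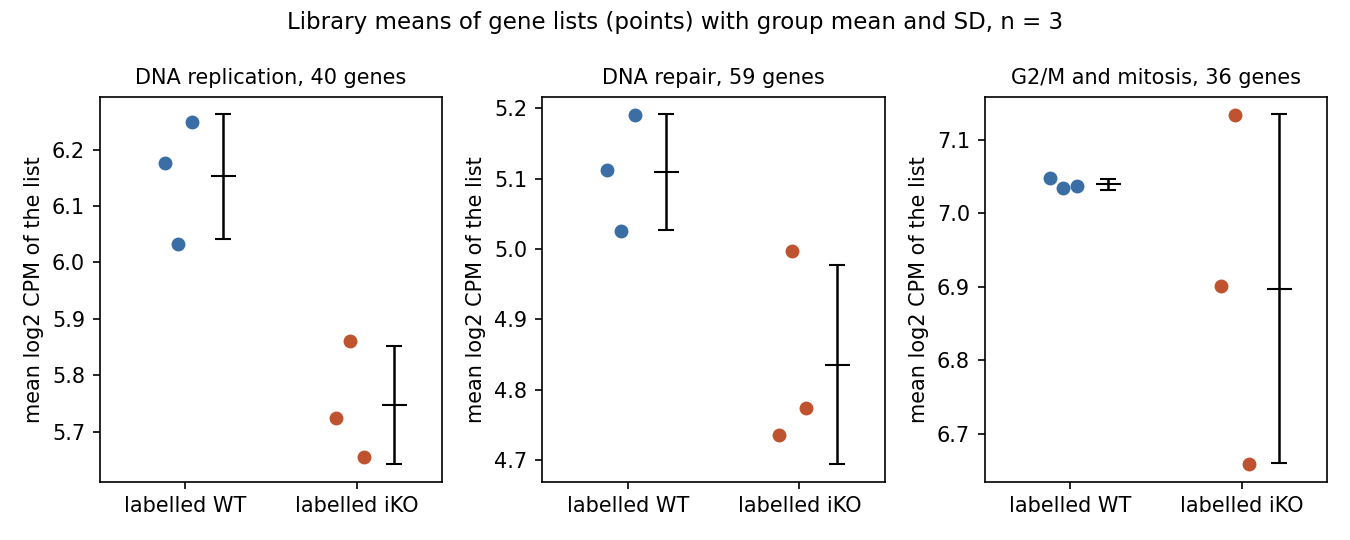
Mean log2 CPM (y axes) of the DNA replication, DNA repair and mitosis lists in each library (points), with the group mean and SD in black (n = 3); the y axes do not start at 0. The replication means lay between 5.66 and 5.86 in the libraries labelled iKO, all below those labelled WT, and the mitosis means of the groups overlapped.

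These were the 3 of 22 lists past an adjusted p of 0.05 in limma's camera test with a preset correlation of 0.01 (3.43e-14, 1.07e-08 and 0.0157). With an estimated correlation none of the 22 passed: adjusted p = 0.851 for each of the 3, and the unadjusted p for replication was 0.0479. Without iKO 33 the mitosis list had a median of -0.03 and a camera adjusted p of 0.775, and without iKO 4 a median of -0.24; over all alternatives the adjusted p reached 0.906. In all, 6 lists passed without WT 2, without WT 4 or without iKO 3. Each of the other 9 ways to split the 6 libraries into groups of 3 also gave between 3 and 10 lists past that threshold. In fry, which asks whether the genes of a list move on balance one way, none of the 22 passed (lowest adjusted p = 0.151, replication), and 9 passed its test for changes in either direction.

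Stress and damage-response lists were mixed. Here and below, a pass over a list alone carries no correction across lists. Of 29 tested p53 target genes, 20 were higher and 9 lower, and 3 passed when adjusted over the list alone: the cell cycle inhibitor gene Cdkn1a (0.72, SE 0.14; 248 ± 14.8 to 407 ± 60.7 CPM), the stress sensor gene Sesn2 (0.63, SE 0.14) and Mdm2, the p53 ubiquitin ligase gene (0.58, SE 0.13). Gadd45a of the same list stood at -0.61 (SE 0.17). Of 20 immediate early genes, 14 were higher and 6 lower, and Ier3 passed over all genes in edgeR, rising from 90.4 ± 6.50 to 184 ± 18.0 CPM. Adjusted over the list alone, Cyr61 (0.87, SE 0.22) and Dusp5 (1.36, SE 0.36) also passed higher and Myc (-0.57, SE 0.12) lower. In the unfolded protein and integrated stress response list (6 higher, 12 lower), Sesn2 was higher and the asparagine synthetase gene Asns (-0.55, SE 0.12) lower when adjusted over the list alone. Gclc, which encodes the catalytic subunit for the first step of glutathione synthesis, was the 1 of 14 NRF2 genes (9 higher, 5 lower) to pass that way (-1.28, SE 0.27). Apoptosis genes (13 higher, 5 lower), cholesterol synthesis genes (5 higher, 15 lower), hypoxia and glycolysis genes (7 higher, 11 lower) and interferon genes (8 higher, 7 lower) had no member past either adjustment in edgeR. An unadjusted p under 0.05 was reached by 2 interferon genes and by 1 gene of each other list among these, and DESeq2 called 1 interferon gene and none of the rest.

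In the keratinocyte lists, single genes passed and no list did in camera. Trp63, the p63 transcription factor gene of basal keratinocytes, stood at 320 ± 12.3 CPM in the libraries labelled WT and 200 ± 7.86 CPM in those labelled iKO (-0.68, SE 0.10). It just missed the threshold over all genes (edgeR adjusted p = 0.0529) and was the 1 of 16 basal genes (8 higher, 8 lower) to pass when adjusted over the list alone. Of 37 differentiation genes, 16 were higher and 21 lower, and the cornified envelope transglutaminase gene Tgm1 passed that way (1.84, SE 0.30), while Grhl3 (1.03, SE 0.25) and Sprr2d (1.31, SE 0.38) did not. Of 19 hair follicle genes, 6 were higher and 13 lower, and Sox21 passed over all genes and the ligand gene Wnt10a (-0.71, SE 0.16) when adjusted over the list alone. Among 16 sebaceous gland and duct genes (8 higher, 8 lower), the lipid droplet gene Plin2 (0.87, SE 0.14) and Fa2h (1.83, SE 0.37) passed higher and Cidea (-1.63, SE 0.28) lower when adjusted over the list alone. Cdh2, the N-cadherin gene, passed in that way among 12 epithelial-mesenchymal transition genes, 9 of them higher (2.76, SE 0.50). Myc passed so among 7 Wnt target genes (4 lower), and the BMP antagonist gene Nog (-1.21, SE 0.24) among 8 BMP target genes (5 lower). Over all genes neither passed in edgeR (adjusted p = 0.121 for Myc and 0.101 for Nog). None of 6 Hedgehog genes (4 lower) or of 3 tested GATA factor and cofactor genes (2 lower) passed in edgeR or DESeq2. An unadjusted p under 0.05 in edgeR was reached by 2 Hedgehog genes and 0 of the GATA list, where Gata3 stood at -0.32 (SE 0.28). The median and the mean of a list differed in sign for the NF-κB target, basal, Wnt and melanocyte lists, and camera's direction was opposite to the median for the NF-κB target, basal and NRF2 lists. For the EDA pathway, fry and camera gave opposite directions.

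Among markers of other cell types, 6 of 8 tested fibroblast genes were higher (median 0.76). The list did not pass in camera (adjusted p = 0.0892, and adjusted p = 0.851 with an estimated correlation). Sparc (442 ± 126 to 976 ± 251 CPM) and Col6a2 (0.378 ± 0.141 to 1.34 ± 0.200 CPM) passed when adjusted over the list alone. Col1a1, a main fibroblast collagen gene, measured 0.106 ± 0.0876 CPM in the libraries labelled WT and 0.204 ± 0.0731 CPM in those labelled iKO, and Dcn and Lum had no count in any library. No tested member of the melanocyte (2 of 4 lower), immune (2 of 3 lower) or endothelial (3 of 3 lower) lists had an unadjusted p under 0.05 in edgeR or was called by DESeq2, and these lists were too small for a set test. Ribosomal protein genes, taken as a sign of RNA quality, were higher in 35 of 38 cases with a median of 0.12 (camera adjusted p = 0.00355, adjusted p = 0.476 with an estimated correlation). None passed singly in edgeR or DESeq2 or had an unadjusted p under 0.05. No mitochondrially encoded gene was in the count table. Reads set aside as not uniquely aligned made up 30.0% ± 0.525 of all counts in the libraries labelled WT and 24.2% ± 2.36 in those labelled iKO (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible).

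The authors' deposited table of the same comparison lists 737 genes past an adjusted p of 0.05, of which 381 were higher and 356 lower in the libraries labelled iKO. It rests on the same 6 libraries and is not independent. Of the 43 edgeR calls, 37 were also past the threshold in the authors' deposited table. Across 12653 genes in both, log2 fold changes had a Pearson r of 0.916 and 99.6% had the same sign. The authors' deposited table gives Gata6 a log2 fold change of 1.23 (adjusted p = 0.00269) and Edaradd one of -0.95 (adjusted p = 1.78e-05). Xist stands at -0.84 in the authors' deposited table and at -9.37 in edgeR. DESeq2 with a prior that shrinks fold changes gave Xist -0.82 on the same libraries, so the sizes in that table and in edgeR are not directly comparable.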

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

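Counts that HTSeq set aside as ambiguous between genes, which no comparison uses, lay above the level of the libraries labelled WT in every library labelled iKO. They made up 1.03% ± 0.0264 of all counts there against 0.944% ± 0.0445 in the libraries labelled WT (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow).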

How the results depend on the processing

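The X and Y exclusion, the chromosome 1 exclusion, the block of the 2 deepest libraries, the fits of numbers 3 and 4 without a block and DESeq2 with a fold change prior were chosen after seeing the data. The 43 called genes became 76 without a count filter, 757 with DESeq2, 744 with DESeq2 with the prior, 152 at an adjusted p of 0.1 and 14 at 0.01; the cause of the differences between tools was not tested. Other scaling factors, the stricter filter, limma-voom, no robust estimation, the fold minimum, both chromosome exclusions and the block of the deepest libraries gave 37 to 61. Leaving out 1 library gave 7 to 31 genes and, by camera, 3 to 6 lists, with fewer libraries in each fit; for iKO the libraries left out were 3, 4 and 33, since no column bears the number 2. An estimated correlation gave 0 lists, leaving out chromosome 1 gave 5 (the cause was not tested), and DESeq2 gave no list test. At an adjusted p of 0.1 the authors' deposited table has 986 genes (502 higher, 484 lower). Gata6 and Edaradd kept their direction in all alternatives fitted and, at an adjusted p of 0.05, passed in DESeq2 (2.59 and -1.06) and in DESeq2 with the prior (1.24 and -0.95) only; in edgeR Edaradd (adjusted p = 0.0727) would pass at 0.1. The cause was not tested, though the prior shrinks fold changes by construction. With the prior and the summary rows left in, DESeq2 gave Xist -0.82, and 706 of its calls were shared with the authors' deposited table (r = 0.994 across genes). A replicate block could be fitted only to the 4 libraries numbered 3 and 4. It called 103 genes, 24 of them among the 43, against 4 in the same libraries without the block. No label says that the numbers pair the samples, and 2 pairs are too few to show it: deviations correlated at 0.297 for number 3 and 0.661 for number 4, and iKO 3 correlated best with WT 2 (0.325). The mitosis median reversed to 0.0196 with this block and 0.0240 in the same libraries without it, with fewer libraries. Among the 23 called genes that the naming rule takes, 453 gene-by-alternative comparisons kept the call in 350, lost it in 103 and reversed in 0. Of 61 uncalled named genes followed here, 42 gained a call in at least 1 and 0 reversed. Apart from Gata6, Edaradd, Edar and Eda, only uncalled genes with an unadjusted edgeR p under 0.05 were followed, which makes a reversal less likely. The median log2 fold change of all genes lay between -0.01 and 0.02 in all alternatives. Depth limits genes near 3 counts in a library, 0.138 CPM in WT 2.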

Other observations

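Both tests on the labels of Gata6 and the tests of runs of neighbouring genes around Edaradd, with and without genes that have near-identical copies, were chosen after the results were seen. The genes and chromosomes in the next paragraphs were also picked after their values were seen.

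Other genes past the threshold in edgeR include the clustered protocadherin genes Pcdhga11 (5.64, SE 0.64) and Pcdhga12 (3.07, SE 0.39), both higher in the libraries labelled iKO; members of this cluster share exons, so their counts are uncertain. Cgn, the cingulin gene of tight junctions, rose from 29.1 ± 2.99 to 58.9 ± 5.57 CPM and Marveld3, another tight junction gene, from 2.80 ± 0.280 to 8.24 ± 0.938 CPM (SD, n = 3). Sulf1, a heparan sulphate endosulphatase gene, rose from 72.6 ± 9.24 to 184 ± 24.5 CPM, and the secreted factor gene Metrnl from 19.2 ± 2.07 to 43.8 ± 6.84 CPM.

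Chromosomes differed in their typical change between the groups. The median log2 fold change was -0.25 over 704 tested genes of chromosome 1 and -0.19 over 467 of chromosome 13, against 0.12 over 688 of chromosome 8 and 0.10 over 420 of chromosome 14. The library means of log2 CPM did not overlap between the groups for these 4 and 6 other chromosomes, 10 of the 19 autosomes. Chance gives 10% for a single chromosome. All are scaled to the same library size and so depend on each other, and the share of chromosomes is no test. Copy number was not measured, so a difference in it on chromosome 1 or 13 stays open.

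Gata6 was higher in the libraries labelled iKO. All 6 libraries lay on the side of their group for Xist, 4 Y-linked genes and Esr1, so none stood apart from its group in these genes. This cannot exclude a single wrong label, or 1 library of each group exchanged. The side for the sex-linked genes was taken from these same data, and the source of the Esr1 reads is not resolved. An exchange of the groups as a whole cannot be told apart from correct labels: Esr1 was at 29.6 CPM or more in every library labelled iKO, which is where a CreERT2 transcript would lie under correct labels, but counts per gene do not resolve the source of these reads. Reads from exons that remain after recombination, the sex of the cells and the presence of Cre also stay open and untested.

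The neighbours of Edaradd were lower together in the libraries labelled iKO. Of runs of autosomal neighbours, 0.122% had a median as low as -0.90, and 3.35% one as low as -0.40 once the 4 genes with near-identical copies were left out; the window was noticed for being low, so a chance run cannot be told apart. A shift of the whole of chromosome 13 cannot be told apart either: 0 of 439 runs on that chromosome were as low with those genes, 10.96% were without them, and a first comparison using the SE of the window median (0.52) did not separate it from the chromosome median of -0.18. Called autosomal genes did not cluster beyond random draws. Within 2 Mb, 4 called genes had a called neighbour of another symbol stem and 6 had one of any symbol. In both counts 10000 random draws gave a 95th percentile of 9. This argues only against strain-derived segments that each hold several called genes. Segments with a single called gene would leave no cluster and stay open, and the counts say nothing of a segment at Edaradd alone. Whether the lower Edaradd level follows Gata6 or a change of the region stays open.

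The DNA replication list was lower in the libraries labelled iKO. Bias from GC content and transcript length was argued against as the whole cause, since the list median stayed at -0.42 after the trend was removed from each library. The SE set against it, 0.10, is that of the group difference of library list means, not of the median. The difference between the replication and mitosis lists changed by -0.26 (SE 0.10) from the libraries labelled WT to those labelled iKO, though WT 3 and iKO 33 nearly met. This argues only against a cause that lowers both lists by the same amount. Whether a lower share of cycling cells would do so was not tested, so that explanation stays open. No single library decided the direction, as the median was -0.34 or lower with any 1 left out. The genotype, the sex of the cells and the presence of Cre coincide with the label and stay open as untested, and Gata6 itself was higher in the libraries labelled iKO. RNA quality was not measured and stays open too. In the libraries labelled iKO 35 of 38 ribosomal protein genes were higher, but library means of that list overlapped between groups (9.50 in iKO 4, 9.52 log2 CPM in WT 3).

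The 10 splits of the 6 libraries are too few for a share under 0.05. The real grouping gave 43 genes, as many or more in 1 of the 10 splits, and the highest of the others gave 0. For lists in camera with a preset correlation the real grouping gave 3, all 10 splits gave as many or more, and the highest of the others gave 10. With an estimated correlation the replication list had an adjusted p of 0.554 to 0.987 in the other splits and 0.851 in the real one. With the preset correlation the replication list passed in 6 of the 9 other splits, with a median size of at most 0.32 against 0.39 in the real one.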
